A study of Cyclocarya paliurus with 9 samples.

How the data were processed

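Messenger RNA of Cyclocarya paliurus leaves was sequenced on an Illumina HiSeq instrument in 9 libraries, 3 for each of 0, 6 and 14 h with 5 µg/mL tunicamycin and 0.5% Triton. Genes are assembled transcript clusters. The assembler, the aligner, the counting tool and any reference were not given in the sources used here. Per the file headers and values, the authors deposited an estimated count of reads per gene and library, not normalised, in which reads shared between transcripts were split, and 39.6% to 43.7% of the values per library are not whole numbers. The authors also deposited FPKM, read counts scaled by gene length and library size, per gene and library. The gene length in bases is given per the file headers, with a median of 829.0 and a range of 201 to 16791. The authors' deposited q-values, which are adjusted p-values of 6 h and 14 h against 0 h, and their UP and DOWN marks were summarised beside the calls made here. The authors' log2 ratio columns are damaged in the table and were not used. The table names the best hits of each gene in the NR, Swiss-Prot and NT databases, and 71274 of 196207 genes have no hit.

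Counts per library summed to between 16673664 and 21990983. A floor of 3 counts corresponds to 0.136 to 0.18 CPM in single libraries, and a gene without a count in a group was set at 3 counts over the group. Counts were rounded to whole numbers. Genes with a mean of at least 1 FPKM over the 9 libraries were kept, which left 71181, of which 39333 had a Swiss-Prot hit. The 3 groups were fitted in 1 model in edgeR 4.0.16 (R 4.3.3) with TMM factors and its quasi-likelihood test, two-sided, without a block, and p-values were adjusted by Benjamini-Hochberg over all genes tested. Genes were called at an adjusted p under 0.05. The SE given with a log2 change is its size divided by the square root of the quasi-likelihood F statistic, not a separate estimate. The biological coefficient of variation was 41.5%.

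The comparisons (6 h with 0 h, 14 h with 0 h and 14 h with 6 h), the filter, the tests, 20 gene lists with 129 gene names, the rule for naming genes and most alternatives were chosen before the data were examined. The plan foresaw limma on log2 FPKM unless the table held raw counts. Since it held estimated counts, edgeR was used and limma became an alternative. The lists cover ER chaperones and folding enzymes, sensors and transcription factors of the unfolded protein response, ER-associated degradation, N-glycosylation, translocon and ER-Golgi transport, heat shock proteins, ribosomal proteins, the proteasome, autophagy, senescence and chlorophyll breakdown, cell death proteases, photosynthesis, the circadian clock, jasmonate, ethylene, pathogenesis-related proteins and WRKY factors, phenylpropanoids and flavonoids, triterpenoids and sterols, antioxidant and detoxification enzymes, and reference genes. A gene belonged to a list when the description of its best Swiss-Prot hit, or of its NR hit where Swiss-Prot gave none, matched a name of the list, so families count many assembled copies. Genes with a hit outside green plants were left out of the lists. Lists with at least 5 members were tested against the other genes with camera at a preset correlation of 0.01, also with an estimated correlation, and with fry of limma 3.58.1, which asks whether the genes of a list move one way without comparing them with other genes. List p-values were adjusted over the 20 lists, and those of 6 lists added after seeing the results over these 6 alone. List medians set members without a count in a group at their bound and leave out members with at most 3 counts in each of the groups compared, for which no fold is given. Medians as fitted cover all members tested. A direction is given for a gene family where its median kept its sign under each scaling tried.

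The genes named in the text follow a fixed rule. It takes the 8 largest rises and 8 largest falls of each comparison among called genes with a mean of at least 5 FPKM in the higher group, separate groups and a description that names a product. It also takes the most abundant gene of each of the 4 most abundant names in each ER list, of IRE1, bZIP60, bZIP17 and ALG7, and of each of the 2 most abundant names in the other lists. All 46 genes the rule gave as called at 6 h, all 51 at 14 h and all 17 for 14 h against 6 h had the 3 libraries of one group beyond the 3 of the other. This is no separate evidence, since a call favours such genes and, for the largest rises and falls, the rule itself asks for it.

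Summed FPKM of lists and CPM (counts scaled to library size) of other organisms were compared by two-sided exact permutation tests in R, with p = 0.1 as the smallest possible value. The overlap of both comparisons with 0 h was set beside 10 simulations of unchanged groups, in which all 9 libraries were drawn anew around the mean of the 0 h libraries and both comparisons shared the drawn 0 h libraries. The plan named the real 0 h libraries, which would have left out their own noise, so this and the fits with separate 0 h libraries were set after seeing the data. The pipeline was tested on simulated data with planted changes in far fewer genes than were called here against 0 h. The adjusted threshold was therefore stricter there, and the shares recovered are not the power of the real comparisons. Of planted 4-fold changes edgeR recovered 37.3% with the 6 h and 25.4% with the 14 h libraries, and of 8-fold changes 72.7% and 66.7%, with 9 and 3 false calls among 71181 genes. The planted list had a set-test p of 1.23e-19 and 1.36e-18, and a random list 0.684 and 0.922. Simulated genes were drawn independently of each other, so these values do not test the set test on lists of correlated genes.

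Of 32 other settings, 26 tested genes and 28 tested lists. Planned ones were limma-trend on log2 FPKM with pseudocounts of 0.1 and 0.5, FPKM scaled by median of ratios, by TMM or by quantiles, limma without its trend and with array weights, DESeq2 1.42.0, no filter, a minimum mean of 5 FPKM, a replicate block, fits of 2 groups at a time, a log2 change of at least 1, green plant hits alone, the most abundant gene of each name alone, an estimated correlation, fry, and each of the 9 libraries left out in turn. Settings added after seeing the data were relative log expression factors in edgeR, edgeR's filterByExpr, library 1 as the sole library of TM_14h, and members with a plant nucleotide hit. The plan named limma on log2 FPKM with a pseudocount of 1 as the main test, and shares of FPKM for other organisms. Both were kept as alternatives to the counts. No scaling moved the median log2 change of all genes by more than 0.1. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. Sequences of other organisms were counted and not examined further.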

Results

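Cyclocarya paliurus, the wheel wingnut, is a tree of the walnut family whose leaves are used as a tea. Pieces of leaf (0.2 g, from 3 individual trees) were exposed to 5 µg/mL tunicamycin with 0.5% Triton, a detergent that helps uptake, and their messenger RNA was sequenced after 0, 6 and 14 h. Tunicamycin blocks the first step of N-glycan assembly, so that secreted proteins misfold in the endoplasmic reticulum (ER), and the series was made to describe the genes of ER stress. Each time was covered by 3 libraries, TM_0h, TM_6h and TM_14h, numbered 1 to 3. The read counts per library summed to 17210160, 18924752 and 17787629 at 0 h, to 16673664, 17757876 and 17584486 at 6 h and to 17228669, 21990983 and 19415556 at 14 h. Leaves kept for 6 or 14 h without tunicamycin were not part of the series. Differences from 0 h therefore combine tunicamycin, Triton, the time spent in the solution and the time of day. The labels do not tie library numbers to trees, so the p-values measure the spread between these samples. Of 196207 assembled genes, 71181 had a mean of at least 1 FPKM (a count scaled by gene length and library size) and were tested. Principal component 1 held 41.4% of the variance and set the TM_0h libraries, between -218.6 and -185.0, apart from the other libraries, between 73.6 and 138.6. Correlations of log2 values across genes, which are not independent replicates, were 0.910 to 0.953 within groups and 0.814 to 0.937 between groups.

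The comparison of 6 h with 0 h asked which genes of the ER stress response moved first. BiP, the main Hsp70 chaperone of the ER lumen (Luminal-binding protein 5, Cluster-29186.93058), rose from 54.9 ± 3.33 to 265 ± 33.9 FPKM (SD, n = 3), a log2 change of 2.23 ± 0.17 (SE) with an adjusted p of 7.5e-05. Calnexin, a lectin chaperone that holds glycoproteins until they fold (Calnexin homolog, Cluster-29186.91844), rose from 69.5 ± 3.28 to 160.4 ± 9.29 FPKM, a log2 change of 1.18 ± 0.14 (adjusted p = 0.000556). Protein disulfide-isomerase, which forms and reshuffles disulfide bonds (Cluster-29186.102307), rose by a log2 value of 0.89 ± 0.13 (adjusted p = 0.00183). By family, 3 of 5 BiP genes, 5 of 6 genes of the chaperone GRP94, 5 of 7 calnexin genes and 9 of 41 genes of protein disulfide-isomerases rose. Of the 108 ER chaperone and folding genes, 35 rose and 0 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 38 and 0 adjusted over the list alone. At an unadjusted p under 0.05, 46 rose and 0 fell, and DESeq2 and limma each called 37 higher and 0 lower. The list's median log2 change was 0.66 without 2 members at or under 3 counts in both groups, or 0.69 as fitted over all members. It passed camera's set test (adjusted p = 8.12e-08) and kept its call with an estimated correlation between genes (adjusted p = 0.0273). The list's summed FPKM went from 1496 ± 66.5 to 2956 ± 113 (n = 3, exact permutation p = 0.1, the smallest that 3 against 3 libraries allow).

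**Figure D1:**
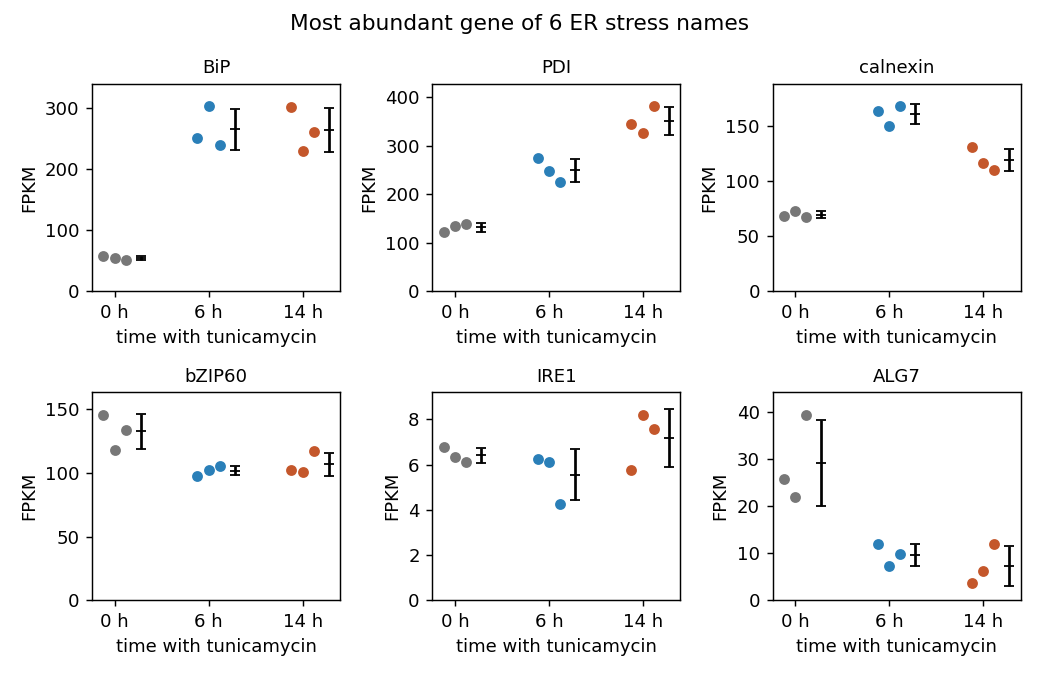
FPKM of 6 ER stress genes against hours with tunicamycin, with 1 dot per library and bars for the mean ± SD of 3 libraries. BiP stands at 54.9 FPKM at 0 h and at 265 and 264 FPKM at 6 and 14 h, while ALG7, the target of tunicamycin, goes from 29.1 to 9.67 and 7.29 FPKM.

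The sensors and transcription factors that switch the ER stress response on changed less evenly at 6 h. Of 4 genes named for bZIP60, the factor that the ER kinase IRE1 activates by splicing its message, 3 rose. The most abundant of them (Cluster-29186.100684) stood at 132 ± 13.9 FPKM at 0 h and 102 ± 3.66 FPKM at 6 h, with a log2 difference of -0.42 ± 0.16 that did not pass the test (adjusted p = 0.102). Without library TM_0h 2 it did (adjusted p = 0.0425), within a range of 0.0304 to 0.255 over its alternatives. The most abundant IRE1 gene (IRE1b, Cluster-29186.137737) had a log2 difference of -0.25 (adjusted p = 0.479), and that for bZIP17 (Cluster-29186.66862), a factor released from the ER membrane by proteases, of 0.82 (adjusted p = 0.147). No gene that passed the expression filter carried a name of bZIP28, NAC103 or the site-2 protease. BAG7, an ER co-chaperone, rose in 4 of 6 genes. In the whole list of 31 sensors and factors 7 rose and 3 fell (10 and 4 adjusted over the list alone), and the set test did not pass (median log2 change 0.02, adjusted p = 0.342, and 0.344 with an estimated correlation). By fry, which does not compare a list with other genes, the list passed (adjusted p = 0.000208).

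N-glycan assembly, the pathway that tunicamycin blocks, had genes moving both ways at 6 h. ALG7, the transferase that tunicamycin inhibits (Cluster-29186.72501), fell from 29.1 ± 9.16 to 9.67 ± 2.34 FPKM at 6 h, a log2 change of -1.62 ± 0.43 (adjusted p = 0.0289). Dehydrodolichyl diphosphate synthase 2, an enzyme of the lipid carrier of the glycan (Cluster-29186.91720), fell from 62.6 ± 7.24 to 9.64 ± 0.428 FPKM, a log2 change of -2.72 ± 0.24 (adjusted p = 0.000128). The oligosaccharyltransferase, which moves the glycan to the protein, had 18 of 41 subunit genes higher, and glucosidase II, which trims it, 5 of 13. Of 131 genes for N-glycosylation 26 rose and 4 fell, the same numbers as adjusted over the list alone, with a median log2 change of 0.40. The set test did not pass (adjusted p = 0.0569, and 0.073 with an estimated correlation). ALG7 lost its call without TM_0h 1 (adjusted p = 0.0577), TM_0h 3 (0.0853), TM_6h 1 (0.0605), TM_6h 2 (0.0893) or TM_6h 3 (0.0629), within 0.00176 to 0.0893 over its alternatives. The list passed without TM_0h 1 (0.0256), TM_0h 3 (0.0357), TM_6h 2 (0.0387), TM_6h 3 (0.0229), TM_14h 1 (0.0247), TM_14h 2 (0.0346) or TM_14h 3 (0.0223), within 0.000152 to 0.523. In all it passed in 21 of 28 alternatives, among them the replicate block (0.0252), the fit of both groups alone (0.00822) and each limma setting.

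Single genes of protein export and of ER-associated degradation rose at 6 h, while neither list passed with an estimated correlation. The beta subunit of the translocon-associated complex, which sits beside the channel for nascent secreted proteins (Cluster-29186.109880), rose from 57.0 ± 5 to 120.5 ± 18.9 FPKM, or 2.09-fold (adjusted p = 0.0021). The gamma subunit of the channel itself, Sec61 (Cluster-29186.78659), rose by a log2 value of 1.03 ± 0.20 (adjusted p = 0.007). Of 260 genes for the translocon and ER-Golgi transport 44 rose and 5 fell (45 and 5 adjusted over the list alone), with a median log2 change of 0.36 (set test, adjusted p = 0.0181). That call was lost with an estimated correlation (adjusted p = 0.0945) and with the most abundant gene of each name alone (0.156). Among genes of ER-associated degradation, which returns misfolded proteins to the cytosol, the ubiquitin ligase RMA1H1 (Cluster-29186.119381) rose from 36.9 ± 2.57 to 81.3 ± 4.45 FPKM, a log2 change of 1.11 ± 0.19 (adjusted p = 0.00336). Of the 119 degradation genes 7 rose and 4 fell (4 and 3 adjusted over the list alone), and the set test did not pass (median 0.15, adjusted p = 0.821, and 0.844 with an estimated correlation). By fry, which does not compare a list with other genes, the degradation list passed (adjusted p = 0.0265).

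The list with the most genes called higher at 6 h was that of cytosolic ribosomal proteins. The small-subunit protein S29 (Cluster-29186.122206) went from 246 ± 73.6 to 967 ± 69.7 FPKM, a log2 change of 2.0 ± 0.38 (adjusted p = 0.00584). Of 605 ribosomal protein genes 429 rose and 2 fell (473 and 4 adjusted over the list alone), with a median log2 change of 2.0 (adjusted p = 1.62e-66), but adjusted p = 0.052 with an estimated correlation. Their summed FPKM went from 8933 ± 1366 to 33028 ± 4663 (n = 3, exact permutation p = 0.1, the smallest possible). Heat shock proteins of the cytosol and organelles, which hold unfolded proteins, rose in 74 of 197 genes and fell in 15 (88 and 19 adjusted over the list alone), with a median of 0.89 (adjusted p = 3.15e-07). The heat shock call was lost with an estimated correlation (adjusted p = 0.0835) and with the most abundant gene of each name alone (0.292). Of 12 HSP90 genes 10 rose, with Heat shock protein 83 (Cluster-29186.101503) going from 99.1 ± 6.35 to 226 ± 15.5 FPKM (log2 change 1.16 ± 0.15, adjusted p = 0.000849). Of 124 reference genes, such as actins, tubulins and elongation factor 1-alpha, 33 rose and 4 fell (35 and 4 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.000345, but 0.0945 with an estimated correlation and 0.29 with the most abundant gene of each name alone). Elongation factor 1-alpha 2, which brings transfer RNA to the ribosome (Cluster-29186.89377), rose by a log2 value of 1.59 (adjusted p = 0.000149).

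Jasmonate, ethylene and defence genes were called in both directions at 6 h. Allene oxide synthase, which commits a fatty acid to jasmonate (Cluster-29186.83032), went from 7.37 ± 2.87 to 219 ± 119 FPKM, a log2 change of 4.86 ± 0.53 (adjusted p = 0.000338). 12-oxophytodienoate reductases, a family that includes a later enzyme of the same pathway, rose in 13 of 25 genes and JAZ repressors of the jasmonate response in 16 of 37. Of 122 jasmonate genes 45 rose and 6 fell (55 and 7 adjusted over the list alone), with a median of 1.05, or 0.98 as fitted (adjusted p = 6.75e-09, but 0.113 with an estimated correlation). Ethylene genes divided. ACC synthases, the limiting step of ethylene production, rose in 3 of 4 genes, while the repressor ERF4 (Cluster-29186.95483) fell from 632 ± 146 to 113 ± 18.8 FPKM (log2 change -2.52 ± 0.23, adjusted p = 0.000159). Of 199 ethylene genes 72 rose and 26 fell (81 and 34 adjusted over the list alone), with a median of 0.50 (adjusted p = 0.000191, but 0.159 with an estimated correlation). With the most abundant gene of each name alone the call was lost and the sign of the test turned negative (adjusted p = 0.919, within 7.3e-05 to 0.919 over its alternatives). All 5 genes for pathogenesis-related protein 1, an antimicrobial protein, rose, and of 218 WRKY factor genes 19 rose and 55 fell. In the whole list of 375 pathogenesis-related and WRKY genes 71 rose and 60 fell (80 and 73 adjusted over the list alone). Its median was -0.21, its mean 0.08 and the sign of its test negative (adjusted p = 0.823, and 0.92 with an estimated correlation). With the most abundant gene of each name alone it passed with a positive sign (adjusted p = 0.00091, within 0.00091 to 0.955).

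Single genes of secondary metabolism and detoxification also rose at 6 h, while the calls of their 3 lists were lost with an estimated correlation. Trans-cinnamate 4-monooxygenase, an early enzyme of phenylpropanoids (Cluster-29186.85191), went from 21.95 ± 7.4 to 419.7 ± 89.9 FPKM, a log2 change of 4.21 ± 0.31 (adjusted p = 7.07e-05). Of 121 phenylpropanoid and flavonoid genes 35 rose and 15 fell (38 and 19 adjusted over the list alone), with a median of 0.08 without the 2 members at or under 3 counts in both groups, or 0.22 as fitted over all members (adjusted p = 0.00502, but 0.117 with an estimated correlation). That call was lost in 10 of 28 alternatives, with adjusted p up to 0.753. Beta-amyrin 28-oxidase, which makes oleanane-type acids (Cluster-29186.94088), rose from 194 ± 14.2 to 638 ± 72.9 FPKM (log2 change 1.69 ± 0.15, adjusted p = 0.000114). Of 93 triterpenoid and sterol genes 27 rose and 4 fell (35 and 4 adjusted over the list alone), with a median of 0.81 (adjusted p = 0.000417, but 0.113 with an estimated correlation). Glutathione S-transferase 3 (Cluster-29186.93069), a detoxifying enzyme, rose from 755.6 to 2196 FPKM (log2 change 1.55, adjusted p = 2e-04). Of 232 antioxidant and detoxification genes 44 rose and 12 fell (45 and 14 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.00527, but 0.113 with an estimated correlation).

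Single genes of leaf ageing, self-digestion and daily rhythm fell at 6 h, while the calls of their 3 lists were lost with an estimated correlation. The senescence factor NAC29 (Cluster-29186.97232) went from 967 ± 93.2 to 239.8 ± 20 FPKM, a log2 change of -2.03 ± 0.20 (adjusted p = 0.000215), and pheophytinase, which breaks down chlorophyll (Cluster-29186.93424), fell by 1.83 on the log2 scale (adjusted p = 0.000265). Of 69 senescence genes 1 rose and 19 fell (2 and 25 adjusted over the list alone), with a median of -0.79 (adjusted p = 2.91e-07, but 0.0663 with an estimated correlation). ATG8C, which tags membranes for autophagy (Cluster-29186.86877), fell from 439 ± 91.9 to 134 ± 4.4 FPKM (log2 change -1.72 ± 0.18, adjusted p = 0.000255). Of 111 autophagy genes 2 rose and 26 fell (3 and 35 adjusted over the list alone), with a median of -0.52, or -0.57 as fitted (adjusted p = 1.68e-06, but adjusted p = 0.052 with an estimated correlation). The pseudo-response regulator APRR5, a repressor of the morning arm of the clock (Cluster-29186.91873), fell from 90.4 ± 4.23 to 29.9 ± 12.3 FPKM (log2 change -1.63 ± 0.29, adjusted p = 0.00461). Of 109 clock genes 43 fell and 0 rose in edgeR's test (50 and 1 adjusted over the list alone), against 59 and 2 at an unadjusted p under 0.05, 51 and 1 in DESeq2 and 42 and 0 in limma. The clock median was -0.77 (adjusted p = 7.89e-14, but 0.0655 with an estimated correlation).

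Photosynthesis, the proteasome and cell death proteases did not pass the set test at 6 h. Of 139 photosynthesis genes 1 rose and 9 fell (1 and 2 adjusted over the list alone), with 8 of the falls among 42 light-harvesting proteins. The list's median was -0.11 (adjusted p = 0.0559, and 0.68 with an estimated correlation). It passed without TM_0h 3 (0.0189), TM_6h 3 (0.000653), TM_14h 2 (0.0385) or TM_14h 3 (0.0385), within a range of 0.000653 to 0.68. In all it passed in 16 of 27 alternatives, among them the replicate block (0.0319), the fit of both groups alone (0.0364) and plant nucleotide hits (0.0328). Of 169 proteasome genes 10 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.522, and 0.641 with an estimated correlation). By fry, which does not compare a list with other genes, the proteasome list passed (adjusted p = 0.00252). Of 23 genes for cell death proteases 4 fell and 0 rose in edgeR's test (2 and 0 adjusted over the list alone), against 4 and 3 at an unadjusted p under 0.05, 4 and 1 in DESeq2 and 3 and 0 in limma. Their median was 0.04, their mean -0.02 and the sign of the test negative (adjusted p = 0.468, and 0.641 with an estimated correlation).

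Among genes with a named product, a mean of at least 5 FPKM in the higher group and no overlap between groups, the largest rises at 6 h included genes without a count at 0 h. A homolog of ACC oxidase (homolog 3, Cluster-29186.100096) stood at 25.9 ± 8.61 FPKM at 6 h, at least 551-fold higher (adjusted p = 0.000319), and the oxidase cytochrome P450 71A2 (Cluster-29186.98445) at 27.97 ± 4.65 FPKM, at least 381-fold higher (adjusted p = 0.000219). Neither had a count at 14 h. The mitochondrial peptidyl-tRNA hydrolase ICT1 (Cluster-29186.99304), which frees stalled ribosomes, was at least 1030-fold higher and the valine-breakdown enzyme 3-hydroxyisobutyryl-CoA hydrolase 1 (Cluster-29186.92480) at least 526-fold higher. Genes that ended at 0 counts at 6 h included SPX3, a repressor of the phosphate starvation response (Cluster-29186.102432), at least 574-fold lower, and protein phosphatase 2C 6 (Cluster-29186.90949), at least 162-fold lower. These bounds put the empty group at 3 counts over its 3 libraries. A switch between assembled copies or alleles was not separated from a change of the gene. In all, 13086 of 71181 genes changed at 6 h, 7812 higher and 5274 lower, and 6747 and 4266 of them by at least 2-fold.

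**Figure D2:**
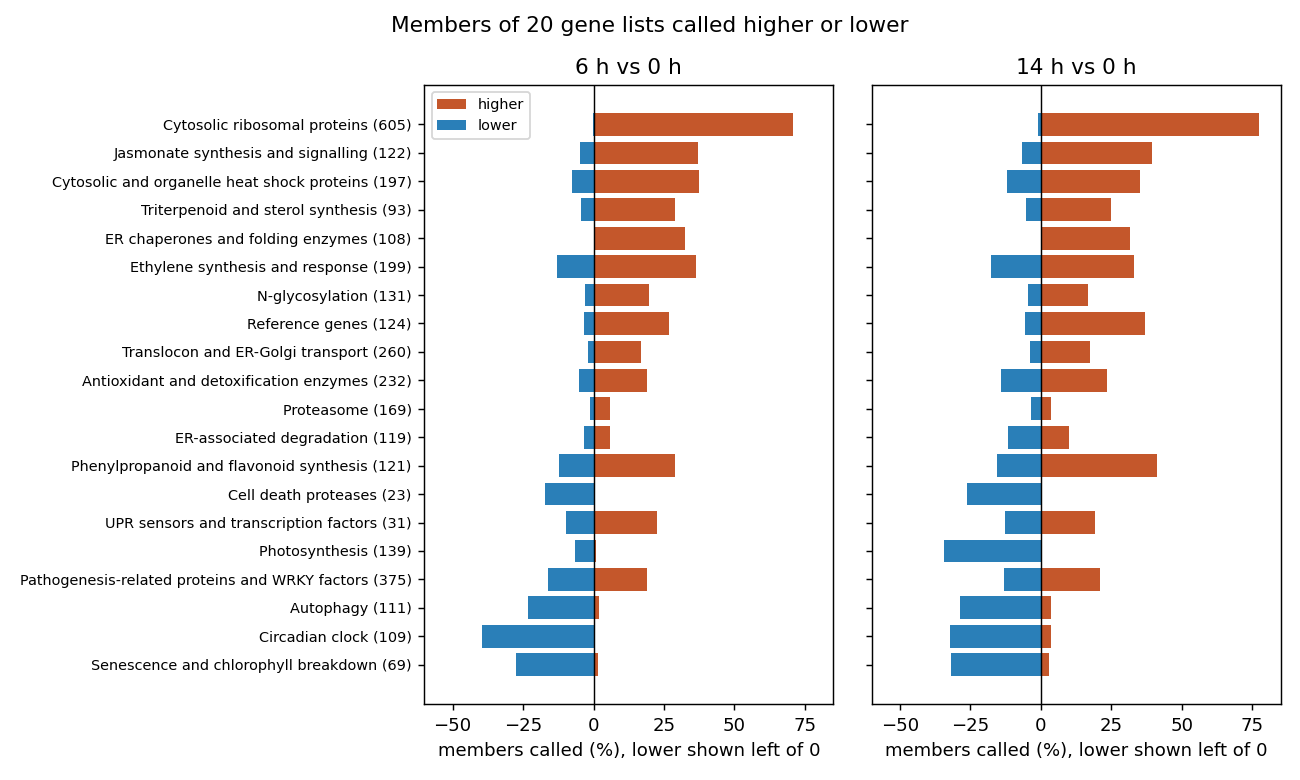
Members of each of 20 gene lists called higher (right of 0) or lower (left of 0), in percent of the members tested, for 6 h and 14 h against 0 h, with the number of members in brackets. Cytosolic ribosomal proteins reach the furthest to the right, with 429 of 605 members higher at 6 h and 468 at 14 h, and 43 of 109 clock genes lie to the left at 6 h.

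The comparison of 14 h with 0 h asked whether the response lasted. BiP stayed high at 264 ± 35.8 FPKM (n = 3), a log2 change of 2.28 ± 0.17 (Cluster-29186.93058, adjusted p = 3.45e-05). Protein disulfide-isomerase (Cluster-29186.102307) stood at 351 ± 28.4 FPKM against 132 ± 9.05 FPKM at 0 h, a log2 change of 1.43 ± 0.14 (adjusted p = 0.000105), and calnexin (Cluster-29186.91844) was higher by 0.80 ± 0.14 (adjusted p = 0.0029). Calreticulin, the soluble partner of calnexin, was higher in 9 of 18 genes. Of the 108 ER chaperone genes 34 rose and 0 fell in edgeR's test (35 and 0 adjusted over the list alone), against 42 and 0 at an unadjusted p under 0.05, 39 and 0 in DESeq2 and 31 and 0 in limma. The list's median was 0.62 (adjusted p = 3.95e-06), and its call held with an estimated correlation (adjusted p = 0.0312). ALG7 (Cluster-29186.72501) was down to 7.29 ± 4.16 FPKM, a log2 change of -1.99 ± 0.44 (adjusted p = 0.00955). Dehydrodolichyl diphosphate synthase 2 (Cluster-29186.91720) was lower by a log2 change of -2.10 ± 0.24 (adjusted p = 0.000254). Bax inhibitor 1, an ER membrane protein that restrains cell death (Cluster-29186.86812), fell from 333 ± 26 to 178 ± 14.3 FPKM (log2 change -0.89 ± 0.16, adjusted p = 0.00339). Its adjusted p was 0.0515 with library 1 as the sole library of TM_14h, the highest of its alternatives, whose lowest was 7.02e-06.

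The other ER lists at 14 h gave mixed results. Sensors and factors rose in 6 and fell in 4 of 31 genes (8 and 5 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.361, and 0.36 with an estimated correlation), and the most abundant bZIP60 gene (Cluster-29186.100684) had a log2 difference of -0.30 (adjusted p = 0.219). The sensor list passed by fry alone (adjusted p = 0.000248). N-glycosylation genes rose in 22 and fell in 6 of 131 (21 and 5 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.103, and 0.105 with an estimated correlation). That list passed without TM_0h 1 (0.0488), TM_6h 1 (0.0462), TM_6h 2 (0.0421), TM_6h 3 (0.0358) or TM_14h 1 (0.0478), within 0.000135 to 0.299, and in 16 of 28 alternatives in all, the replicate block (0.0396) among them. Translocon and transport genes rose in 45 and fell in 10 of 260 (40 and 9 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0249, but 0.127 with an estimated correlation and up to 0.302 over its alternatives). Degradation genes rose in 12 and fell in 14 of 119, as they did adjusted over the list alone. Their median of 0.06 and mean of 0.08 were positive and the sign of their test negative (adjusted p = 0.996, also with an estimated correlation). The ligase RMA1H1 (Cluster-29186.119381) reached 93.1 ± 17.3 FPKM (log2 change 1.36, adjusted p = 0.000821). The ubiquitin fusion degradation protein 1 homolog (Cluster-29186.109859) was called lower, with log2 changes of -0.80 to -0.69 over its alternatives. It kept its call in 25 of 26 of them. The named genes for CDC48 and the ubiquitin-conjugating enzyme E2 32 were not called.

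At 14 h the ribosomal protein list was higher than at 0 h, also with an estimated correlation, and the photosynthesis list lower, a call that was lost with one. S29 (Cluster-29186.122206) stood at 1533 ± 279 FPKM (log2 change 2.69, adjusted p = 0.000953), and 468 of 605 ribosomal genes were higher and 6 lower (508 and 8 adjusted over the list alone). The ribosomal median was 2.46, or 2.47 as fitted (adjusted p = 1.27e-80, and 0.0312 with an estimated correlation), and the summed FPKM was 46963 ± 5258 (n = 3). The photosystem II 10 kDa protein of the oxygen-evolving complex (Cluster-29186.93736) fell from 509 ± 41.3 to 182 ± 56.5 FPKM (log2 change -1.47 ± 0.23, adjusted p = 0.00177). Of 139 photosynthesis genes 48 fell and 0 rose in edgeR's test (52 and 0 adjusted over the list alone), against 69 and 0 at an unadjusted p under 0.05, 55 and 0 in DESeq2 and 50 and 0 in limma. Their median was -0.76 (adjusted p = 4.13e-11, but 0.173 with an estimated correlation). Heat shock proteins rose in 69 and fell in 24 of 197 genes (76 and 26 adjusted over the list alone), with a median of 0.79 (adjusted p = 5.82e-05, but 0.149 with an estimated correlation and 0.541 with the most abundant gene of each name alone). Reference genes rose in 46 and fell in 7 of 124 (49 and 9 adjusted over the list alone), with a median of 0.54, or 0.40 as fitted (adjusted p = 1.07e-05, but 0.0683 with an estimated correlation and 0.302 with the most abundant gene of each name alone). Proteasome genes rose in 6 and fell in 6 of 169 (1 and 1 adjusted over the list alone), with a median of 0.03, a mean of 0.06 and a negative sign of the test (adjusted p = 0.92, and 0.934 with an estimated correlation).

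Jasmonate, phenylpropanoid and triterpenoid genes were more often called higher than lower at 14 h, and of these 3 lists that of phenylpropanoids alone kept its call with an estimated correlation. Allene oxide synthase (Cluster-29186.83032) was still higher than at 0 h (log2 change 5.84 ± 0.55, adjusted p = 0.000105) and 12-oxophytodienoate reductase 1 (Cluster-29186.96251) 1220 ± 326 FPKM against 106 ± 22.7 FPKM at 0 h (log2 change 3.55 ± 0.34, adjusted p = 0.000107). Jasmonate genes rose in 48 and fell in 8 of 122 (57 and 11 adjusted over the list alone), with a median of 0.90 (adjusted p = 2.5e-07, but 0.157 with an estimated correlation). Ethylene genes rose in 66 and fell in 35 of 199 (77 and 42 adjusted over the list alone), with a median of 0.44 (adjusted p = 0.0204). The ethylene call was lost with an estimated correlation (adjusted p = 0.36) and without TM_0h 2 (0.0968), and with the most abundant gene of each name alone the sign of the test turned negative (0.692), within a range of 0.0057 to 0.692. Phenylalanine ammonia-lyase, the entry to phenylpropanoids (Cluster-29186.95040), rose from 295 ± 41.3 to 795 ± 94.2 FPKM (log2 change 1.45, adjusted p = 0.000397). Phenylpropanoid genes rose in 50 and fell in 19 of 121 (56 and 21 adjusted over the list alone), with a median of 0.81 (adjusted p = 1.03e-06, and 0.0402 with an estimated correlation). HMG-CoA reductase 1, the step that limits the supply of triterpenoids (Cluster-29186.95278), was higher by a log2 value of 1.58 (adjusted p = 0.00281). Triterpenoid and sterol genes rose in 23 and fell in 5 of 93 (27 and 5 adjusted over the list alone), with a median of 0.74 (adjusted p = 0.00221, but 0.172 with an estimated correlation and 0.0567 with the most abundant gene of each name alone). Antioxidant and detoxification genes rose in 54 and fell in 33 of 232 (55 and 38 adjusted over the list alone). Their median was -0.11, while their mean of 0.29 and the sign of their test were positive (adjusted p = 0.357, and 0.476 with an estimated correlation). The antioxidant list passed by fry alone (adjusted p = 0.00644). Pathogenesis-related and WRKY genes rose in 78 and fell in 49 of 375 (82 and 58 adjusted over the list alone), with a median of 0.10 (adjusted p = 0.62, and 0.882 with an estimated correlation). They passed with the most abundant gene of each name alone (adjusted p = 0.00193, within 0.00193 to 0.994).

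The senescence and autophagy lists were lower at 14 h than at 0 h, also with an estimated correlation, while the clock call was lost with one. NAC29 (Cluster-29186.97232) was at 154 ± 40.3 FPKM (log2 change -2.63, adjusted p = 4.22e-05) and ATG8C (Cluster-29186.86877) at 90.2 ± 5.04 FPKM (log2 change -2.24, adjusted p = 4.81e-05). Senescence genes rose in 2 and fell in 22 of 69 (4 and 25 adjusted over the list alone), with a median of -0.81 (adjusted p = 5.42e-08, and 0.0402 with an estimated correlation). Autophagy genes rose in 4 and fell in 32 of 111 (6 and 37 adjusted over the list alone), with a median of -0.81 (adjusted p = 1.03e-06, and 0.0312 with an estimated correlation). Clock genes rose in 4 and fell in 35 of 109 (5 and 38 adjusted over the list alone), with a median of -0.54 (adjusted p = 5.24e-07, but 0.127 with an estimated correlation and 0.146 with the most abundant gene of each name alone). Cell death proteases fell in 6 and rose in 0 of 23 genes in edgeR's test, as adjusted over the list alone, against 8 and 0 at an unadjusted p under 0.05, 7 and 0 in DESeq2 and 6 and 0 in limma. Their median was -0.63 (adjusted p = 0.0159, but 0.161 with an estimated correlation, 0.119 without a filter and 0.0554 with filterByExpr).

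For several lists the summed FPKM, which abundant members dominate, did not follow the median of the members at one or both times. The summed FPKM of sensors and factors went from 909.6 ± 66 at 0 h to 702.5 ± 35 at 6 h and 620.3 ± 46.8 at 14 h (n = 3, exact permutation p = 0.1 at both times, the smallest possible), beside medians of 0.02 and 0.40. Reference genes had 0.91 of their 0 h sum at 6 h and 0.90 at 14 h (exact permutation p = 0.4 and 0.1), beside medians of 0.38 and 0.54. Ethylene genes had 1.05 times their 0 h sum at 6 h and 0.90 at 14 h (exact permutation p = 0.5 and 0.1), beside medians of 0.50 and 0.44. Pathogenesis-related and WRKY genes had 1.33 and 1.71 times their 0 h sum (exact permutation p = 0.2 and 0.1), beside medians of -0.21 and 0.10. Antioxidant genes had 1.37 times their 0 h sum at 14 h (exact permutation p = 0.1), beside a median of -0.11, and cell death proteases 0.76 at 6 h (p = 0.1), beside 0.04. Phenylpropanoid genes had sums of 4418 ± 844.6 at 0 h and 4400 ± 259 at 6 h (n = 3), beside medians of 0.08, or 0.22 as fitted. ER-associated degradation and the proteasome had 0.94 and 0.95 of their 0 h sums at 14 h (exact permutation p = 0.4 and 0.3), beside medians of 0.06 and 0.03.

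The largest rise at 14 h by the same rule was that of PGR5, a thylakoid protein of cyclic electron flow (Cluster-29186.117726). It had no count at 0 h, 5.80 ± 9.28 FPKM at 6 h and 405 ± 160 FPKM at 14 h, at least 14300-fold higher than at 0 h (adjusted p = 0.00532). The ribosomal protein L26-1 (Cluster-29186.44638) was at least 434-fold higher and the transcriptional adaptor BT4 (Cluster-29186.151383), with BTB and TAZ domains, at least 308-fold higher. Protein phosphatase 2C 6 (Cluster-29186.90949) was at least 176-fold lower, and choline kinase 1, which feeds membrane lipid synthesis (Cluster-29186.119637), at least 68.8-fold lower. In all, 16418 genes changed at 14 h, 9158 higher and 7260 lower, and 8158 and 5819 of them by at least 2-fold. Floors cover counting error alone.

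The direct comparison of 14 h with 6 h asked what changed late, and equally whether changes from 0 h differed between both times. GDP-L-galactose phosphorylase, the step that sets ascorbate synthesis (Cluster-29186.21193), rose from 0.463 ± 0.203 to 12.5 ± 2.9 FPKM, a log2 change of 4.77 ± 0.47 (adjusted p = 0.0115). Chalcone synthase 1, the entry to flavonoids (Cluster-29186.103643), went from 58.5 ± 27.8 FPKM at 0 h to 5.40 ± 3.15 FPKM at 6 h and 60.2 ± 11.1 FPKM at 14 h, a log2 change of 3.54 ± 0.49 between 6 and 14 h (adjusted p = 0.0223). ACC oxidase homolog 3 (Cluster-29186.100096), present at 6 h, was at least 587-fold lower at 14 h. In edgeR 382 genes changed, 187 higher and 195 lower, against 10301 at an unadjusted p under 0.05 and 3288 in DESeq2. The count fell to 12 with a replicate block. It was 203 without TM_0h 1, 15 without TM_6h 1, 168 without TM_6h 2, 90 without TM_6h 3, 136 without TM_14h 1, 28 without TM_14h 2 and 216 without TM_14h 3. Chalcone synthase lost its call without TM_6h 1 (adjusted p = 0.0817), TM_14h 1 (0.0559) or TM_14h 2 (0.0735), within a range of 1.75e-11 to 0.192. Each gene named here lost its call with library 1 as the sole library of TM_14h, at an adjusted p of 0.152 for the phosphorylase (range 9.92e-25 to 0.152) and 0.121 for the oxidase (range 5.43e-17 to 0.121).

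By list, photosynthesis genes were lower and phenylpropanoid and flavonoid genes higher at 14 h than at 6 h in the set test, calls that were lost with an estimated correlation. Photosynthesis genes had a median of -0.75 (adjusted p = 3.39e-20, but 0.263 with an estimated correlation), with 1 gene called lower and 39 adjusted over the list alone. Phenylpropanoid genes had 10 higher and 1 lower of 121 (27 and 9 adjusted over the list alone), with a median of 0.23 (adjusted p = 1.78e-05, but 0.21 with an estimated correlation). Ribosomal genes had a median of 0.43 (adjusted p = 4.2e-13, but 0.429 with an estimated correlation), with 2 genes called higher and 27 adjusted over the list alone. Clock genes had 4 higher (median 0.14, adjusted p = 0.00432, but 0.479 with an estimated correlation) and cell death proteases a median of -0.41 (adjusted p = 0.00342, but 0.263). Antioxidant genes had 1 higher and 2 lower (median -0.27, adjusted p = 0.00941, but 0.263), ethylene genes 2 higher and 4 lower (median -0.17, adjusted p = 0.0458, but 0.597) and reference genes 1 higher (median 0.19, adjusted p = 0.0429, but 0.429). The ER chaperones had a median of -0.09 (adjusted p = 0.811, and 0.867 with an estimated correlation) and the jasmonate genes a median of -0.03 with a positive sign of the test (adjusted p = 0.96, and 0.983). Without TM_6h 3 the antioxidant (0.1) and clock (0.0638) calls were lost. The ethylene call was lost without TM_0h 1 (0.0732), TM_0h 2 (0.0664), TM_0h 3 (0.11), TM_6h 3 (0.586), TM_14h 1 (0.0612) or TM_14h 3 (0.382), and the reference call without TM_6h 1 (0.0505), TM_6h 2 (0.296) or TM_14h 1 (0.261). Over all alternatives the adjusted p ranged from 0.00388 to 0.263 for antioxidant, from 0.00279 to 0.81 for clock, from 0.016 to 0.81 for ethylene and from 0.00142 to 0.91 for reference genes.

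Most genes called at 6 h were called in the same direction at 14 h. Both comparisons called 6276 genes higher and 3867 lower, against 1005 and 538 for unrelated calls, and 5 genes in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.745. Sharing the TM_0h libraries alone gave r = 0.502 on average over 10 simulations without change, with 0.513 as the highest, and 0 shared calls in edgeR. Groups without change give few calls, so these 0 shared calls were to be foreseen. The covariance of the log2 changes was 1.772, against at most 0.318 in the simulations. With separate TM_0h libraries for each comparison, 1 for one and 2 for the other, r was 0.391 to 0.517 and the covariance 1.317 to 1.54. The simulated r of 0.502 comes from shared TM_0h libraries and is no reference for these fits, for which none was simulated.

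In the table deposited by the authors, the marks were UP for 4070 genes and DOWN for 2673 at 6 h, and for 7376 and 4567 at 14 h. Of these, 3362 and 2083 at 6 h and 5823 and 3730 at 14 h passed the filter and were tested here. Among the tested genes, 3171 and 1905 at 6 h and 5453 and 3482 at 14 h were called in the same direction, and 0 in the opposite direction by edgeR. Of the genes marked UP at 14 h, 204 had a best hit in an organism other than a green plant.

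Reads of other organisms were given as CPM, the count scaled to library size, since leaves carry microbes. Genes with a best nucleotide hit in Agaricus, the genus of the button mushroom, had 2, 1 and 2 counts in the TM_0h libraries, 5, 5 and 4 in the TM_6h libraries and 61, 23920 and 24807 in the TM_14h libraries. Their 789.7 ± 687.4 CPM at 14 h (SD, n = 3) against 0.09 ± 0.04 at 0 h gave an exact permutation p of 0.1, the smallest possible. Genes of other fungi had 285 ± 9.15, 494 ± 85.6 and 727 ± 391 CPM at 0, 6 and 14 h (n = 3, exact permutation p = 0.1 against 0 h at both times), with 54 of 163 tested genes higher at 14 h. The TM_14h libraries spread from 387.0 to 1155 CPM, and library 3, at 387.0 CPM, lay below all 3 TM_6h libraries (433.5 to 591.8 CPM, exact permutation p = 0.5 for 14 h against 6 h). Bacteria had 136 ± 20.6, 154 ± 42.2 and 148 ± 25.1 CPM (n = 3, exact permutation p = 0.7 at 6 h and 0.6 at 14 h). All of these tests were two-sided.

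**Figure D3:**
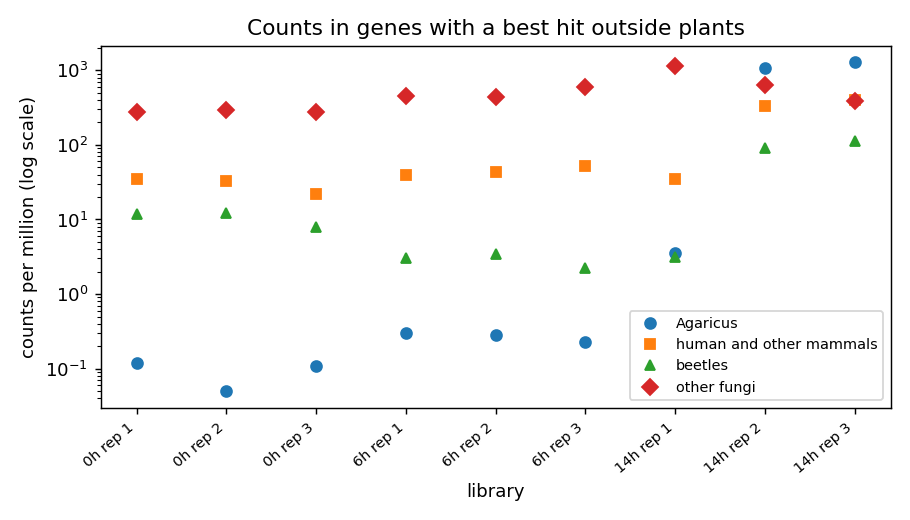
CPM on a log axis for genes with best hits in Agaricus, mammals, beetles and other fungi, with 1 marker per source for each library, in order of time. Agaricus lies above 1000 CPM in libraries 2 and 3 of TM_14h alone, at 1088 and 1278.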

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

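The tests of the fungal counts beyond Agaricus were chosen after their rise was seen. Those of Agaricus between both libraries compare the libraries in which its reads had been seen to be high. Their choice thus also followed from the data, since the plan named only shares of FPKM for other organisms. Groups of 3 libraries are too small for a test of single outliers.

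Reads of a mushroom, mammals and beetles were raised in libraries 2 and 3 of TM_14h, outside what the comparisons measure. In the other libraries Agaricus genes had at most 3.54 CPM, mammal genes 21.93 to 51.35 and beetle genes 2.27 to 12.21. In libraries 2 and 3 of TM_14h Agaricus genes had 1087.7 and 1277.7 CPM, genes of human and other mammals 335.6 and 397.1, and genes of beetles 89.5 and 112.2. The counts per gene of Agaricus in both libraries were proportional nearly within counting error, with a chi-square per degree of freedom of 1.22 over 949 genes, against 8.06 for other fungi and 6.2 for plant genes of like counts. Separate growth of Agaricus on each sample was predicted to give a spread like that of the other fungi, 8.06, which was not seen. The other fungi are a mixed group and were not matched on counts, so this comparison cannot decide against separate growth. The spread of Agaricus also lay below the 6.2 of plant genes of like counts. A common source of RNA or reads behind both libraries may explain the pattern. Mammals gave 1.1, while beetles gave 2.0, above the bound of 1.5 set for Agaricus, and whether the source entered at the leaf, in the laboratory or in sequencing stays open.

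Genes of other fungi had a mean of 727.3 CPM at 14 h, above their level at 0 h, although TM_14h 3, at 387.0 CPM, lay below all 3 TM_6h libraries. They already stood at 493.8 CPM at 6 h, above all 3 TM_0h libraries, where Agaricus had at most 5 counts per library, which argues against the source of the Agaricus reads as the whole cause. Growth of fungi on the leaves under tunicamycin cannot be told apart from growth on any leaf kept as long, since 0 libraries of untreated leaves at 6 h or 14 h exist in the series.

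A set of 382 genes changed from 0 h by different amounts at 6 h and 14 h in the direct test of 14 h against 6 h. Their number moved with single libraries, between 15 without TM_6h 1 and 518 without TM_0h 3. It was 203 without TM_0h 1, 168 without TM_6h 2, 90 without TM_6h 3, 136 without TM_14h 1, 28 without TM_14h 2 and 216 without TM_14h 3.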

How the results depend on the processing

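The settings with relative log expression factors, filterByExpr, library 1 as the sole library of TM_14h and plant nucleotide hits were chosen after seeing the data. Limma on log2(FPKM + 1) and shares of FPKM were named as main in the plan and kept as alternatives. The ER chaperone list kept its call at 6 h and 14 h under all 28 settings that tested lists, with adjusted p from 1.03e-08 to 0.0273 and from 6.07e-07 to 0.0312. Across 5041 results of named genes under alternatives, 4660 kept their side of the threshold, 313 lost a call, 68 gained one and 0 reversed, by the tools named with each setting. Of 1665 list results, 1493 kept their side, 101 lost a call, 68 gained one and 3 reversed. With the most abundant gene of each name alone, ethylene genes reversed at 6 h (adjusted p = 0.919) and 14 h (0.692), and pathogenesis-related and WRKY genes passed upward at 6 h (0.00091) and, without a change of sign, at 14 h (0.00193). The ranges over alternatives were 7.3e-05 to 0.919, 0.0057 to 0.692, 0.00091 to 0.955 and 0.00193 to 0.994.

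The number of lists called, 13 at 6 h, 14 at 14 h and 8 for 14 h against 6 h, was 1, 5 and 0 with an estimated correlation in camera (9, 7 and 2 at an unadjusted p under 0.05, with 5 lists by fry for 14 h against 6 h). It was 7, 5 and 1 with the most abundant gene of each name alone, which leaves fewer members. There 5 lists (ribosomal proteins, autophagy, photosynthesis, cell death proteases and the proteasome) had too few names to be tested, so part of that drop is untested lists. It was 5 for 14 h against 6 h without a filter. The 382 genes of 14 h against 6 h became 213 without a filter, 207 with filterByExpr, 842 at a minimum of 5 FPKM, 12 with a replicate block, 617 in limma, 730 with quantile normalization, 1609 with array weights and 3288 in DESeq2. With library 1 as the sole library of TM_14h, assumed to vary like the other groups, they were 0 in edgeR (4891 at an unadjusted p under 0.05, 721 in DESeq2 and 344 in limma). The 14 h call count then fell to 6709 and the overlap to 5209, with fewer samples. Apart from fewer samples or members, the cause was not tested.

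Leaving out 1 library at a time gave 8833 to 11606 genes at 6 h, 11767 to 18204 at 14 h and 15 to 518 for 14 h against 6 h. The lists called were 13 to 15, 13 to 15 and 6 to 9, the overlap held 7160 to 9248 genes, and the share of other fungi at 14 h was 1.8 to 3.15 times that at 0 h. By summed FPKM with all libraries it was 3.87 times. The lowest 6 h count (8833) was that without TM_0h 1. Genes for 14 h against 6 h were 203 without TM_0h 1, 15 without TM_6h 1, 168 without TM_6h 2, 90 without TM_6h 3, 136 without TM_14h 1, 28 without TM_14h 2 and 216 without TM_14h 3. Library numbers did not clearly pair the samples. Deviations of log2 values from group means correlated at -0.12 to 0.11 between libraries of the same number and at -0.14 to 0.23 between others. Of 9 libraries, 1 correlated best with its own number in both other groups, and the replicate block is no pairing by tree. Depth limits the bounds for genes without a count. The simulated data held far fewer changed genes than were called against 0 h, which makes the adjusted threshold stricter. There edgeR found 1.5% of 2-fold changes with the 6 h libraries and 0% with the 14 h libraries, which is not its power on the real data.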

Other observations

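The tests of ribosomal protein transcripts and 6 further gene lists were chosen after the results were seen, while the splits of the libraries were set before.

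Other splits of the 6 libraries of a comparison, 10 with the real one, are too few for a share under 0.05. Each other split puts libraries of both times in each group, so a real difference adds to the spread within groups. Few genes called in the other splits were thus set in advance and do not measure false calls. At 6 h against 0 h 1 split, the real one, called as many as 13086 genes, with 1 as the highest other, and 1 split as many as 13 lists, with 11 as the highest other. At 14 h against 0 h 1 split called as many as 16418 genes, with 1 as the highest other, and 2 splits as many as 14 lists, with 14 as the highest other. For 14 h against 6 h 1 split called as many as 382 genes, with 1 as the highest other, and 2 splits as many as 8 lists, with 9 as the highest other.

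Transcripts of cytosolic ribosomal proteins were higher at both times in camera's set test at the preset correlation. With an estimated correlation the call was lost at 6 h (adjusted p = 0.052) and kept at 14 h (0.0312). Against genes of matched length their median log2 change was higher by 1.94 at 6 h (95% bootstrap interval 1.88 to 2.02) and by 2.47 at 14 h, which argues against gene length as the cause. The bootstrap drew genes, not libraries, so its intervals leave out the spread between samples and treat genes of the list as independent. Members with a plant nucleotide hit, 559 of 605, had a median of 2.02 at 6 h (1.95 to 2.1) and 2.51 at 14 h. The list had already left out genes with a hit outside green plants. With 559 of 605 members kept the median could hardly move, so this could not test reads from fungi or animals. The summed FPKM of all 605 members was 3.7 times as high at 6 h as at 0 h and 5.26 times at 14 h, with no overlap of the groups, which argues against reads moved between near-identical assembled copies. Tunicamycin treatment cannot be told apart from the time in the solution or the time of day as the cause, since the series holds 0 libraries of untreated leaves at 6 h or 14 h.

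Factors of ribosome biogenesis rose with the ribosomal proteins, in 63 of 137 genes at 6 h and 79 at 14 h, with 1 gene lower at each time and a median log2 change of 1.1 at 6 h and 1.40 at 14 h (adjusted p = 2.02e-16 and 1.17e-22, and 0.0146 and 0.00931 with an estimated correlation). Translation initiation factors rose in 44 and fell in 4 of 186 genes at 6 h and rose in 63 and fell in 5 at 14 h (medians 0.42 and 0.49, adjusted p = 0.000238 and 1.75e-05, and 0.0146 and 0.00931 with an estimated correlation). Elongation factors rose in 16 and fell in 1 of 48 genes at 6 h and rose in 22, with none called lower, at 14 h (medians 0.81 and 0.67, adjusted p = 7.91e-05 and 6.55e-07, and 0.0364 and 0.0159 with an estimated correlation). Mitochondrial ribosomal proteins rose in 17 of 44 genes, with none called lower, at 6 h and rose in 20 and fell in 1 at 14 h (medians 0.85 and 0.90, adjusted p = 8.3e-06 and 1.75e-05, but 0.144 and 0.16 with an estimated correlation). Chloroplast ribosomal proteins rose in 8 and fell in 1 of 107 genes at 6 h and rose in 3 and fell in 16 at 14 h. Their medians were 0.01 and -0.32 (adjusted p = 0.807 and 0.0143, and 0.951 and 0.526 with an estimated correlation). Histones rose in 11 and fell in 2 of 48 genes at 6 h and rose in 10 and fell in 2 at 14 h (medians 0.48 and 0.35, adjusted p = 0.0444 and 0.0613, and 0.296 and 0.363 with an estimated correlation).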
